A study of Caenorhabditis elegans with 2 samples.

How the data were processed

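Chromatin immunoprecipitation with an anti-GFP antibody was carried out on whole starved L1 larvae of the nematode Caenorhabditis elegans, per the labels' description. Another label field names nhr-19 as the antibody, and the description was followed here. The worms carried a fosmid transgene that expresses the nuclear hormone receptor gene nhr-19 fused to EGFP, together with an unc-119 rescue marker in an unc-119 mutant. Age was given as 6 h, and chromatin was sonicated to fragments of 200 to 800 bp, per the labels. The series holds 1 group of 2 biological replicates, numbered 1 and 2 in the labels, and no second condition, so no group was compared with another group.

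The deposited files are 8 peak lists on the ce11 assembly, per the labels. For each replicate there is a ranked list and a thresholded list, and for the series as a whole there are a pair of lists from the true replicates and a pair from pseudoreplicates of the pooled reads. Each peak has a signal value from the authors' peak caller, which is the height measure of that peak in the deposited list and was used only to rank or describe peaks within a list. The ranked lists also hold the −log10 of the global irreproducible discovery rate (IDR) as the authors deposited it. In all 4 pairs, each thresholded peak was found in its ranked list, and the thresholded list equals the ranked peaks with an IDR at or under about 0.01, apart from 16 to 26 peaks that were dropped for a reason not given in the sources used here. Peak caller, aligner and control used are not given in the sources used here. The peak lists hold no read counts, so the depth of each library is unknown. Signal of peaks called on pooled reads grows with depth and is not comparable between lists. The 2 lists of the pooled ranked kind hold 16 columns on single replicates that carry no sample name, and these were not used. Chromosome names and lengths of the reference genome (Ensembl release 115 annotation, WBcel235) were compared with the files, and all peaks of the 6 nuclear chromosomes end within them.

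The list from the true replicates, with 4560 peaks, was taken as the main list. Summits within 200 bp of each other were merged into 1 site, the one of highest signal, which gave 4530 sites. The background was the 15775 candidate sites of the ranked list that failed the threshold and lay over 500 bp from a passing summit. Replicates 1 and 2 had 3763 and 3729 sites after merging. A site was called shared when a summit of the other list lay within 200 bp. The overlap of randomly placed sites came from 1000 circular shifts of one list along its chromosomes. Site classes followed the annotation in this order of priority: promoter (1000 bp upstream to 500 bp downstream of a protein-coding 5′ end), exon, intron, within 500 bp of a non-coding RNA gene, and other intergenic. A gene was called bound when a site lay in its promoter window. Its background was the 6683 protein-coding genes with a site or a candidate in that window. The 28 gene lists and 13 motifs were fixed before the data were examined. Motifs and all 6-mers were sought within 50 bp of each summit and compared with a window of the same width centred 200 bp to the left.

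Shares were compared with Fisher's exact test and paired windows with the exact McNemar test, 2-sided, with Benjamini-Hochberg adjustment within each family. Mean log2 signal was compared, and signal correlated across sites, with 100000 permutations. Log2 odds ratios had 0.5 added to each cell. For motifs and 6-mers against flanks, the paired log2 ratio compares sites with the word only at the summit with sites with it only in the flank. Each of these counts also had 0.5 added. This paired ratio is not the ratio of the shares printed beside it. Intervals of shares are 95% Wilson intervals. Sites and genes, not replicates, are the units of these tests, so p-values do not measure the spread between cultures. The replicates are described by the labels as biological. Tests were checked on simulated data. At an odds ratio of 6 planted in 5 lists over 6683 background genes, 100% of planted lists were called and 1.23% of the others. The planted lists were the 5 with the most background genes, so this share does not carry over to smaller lists or smaller odds ratios. Bound status was drawn for each gene alone, whereas neighbouring genes can share a site. A word planted in 5% of 4530 windows was called, with 3 further words, all of which share 5 bases with it. Both sides of that simulation were shuffled flank windows of equal base composition. It therefore does not show how many calls come from a difference in GC content between summits and flanks.

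Named genes followed a rule fixed before the data were examined. The rule takes nhr-19 and unc-119, the 25 strongest sites found in both replicates with the gene of nearest 5′ end, the 4 bound genes of highest signal in each list that was not lower than its background, the 5 strongest sites over 1000 bp from any 5′ end, and the 5 strongest sites of each replicate that are absent from the other replicate's ranked list, with at most 30 genes per comparison. Alternatives to each choice were also fixed beforehand. As the lists already stop at an IDR of 0.01, the stricter alternative was the strongest 50% of sites. A looser list at an IDR of 0.05, a mapping of each site to its nearest gene only and a pairing of each site once were added after the data were seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.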

Results

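Sites enriched by chromatin immunoprecipitation of GFP-tagged NHR-19, a nuclear hormone receptor, were mapped by sequencing in whole starved L1 larvae of C. elegans. The control is unknown and no other protein's data were used, so signal not specific to NHR-19 was not set apart. A gene is called bound below where a site lay in its promoter window. There were 2 biological replicates of 1 group, and the depth of the libraries is unknown. The list from the true replicates held 4530 sites. The signal of a peak is the authors' own value and ranks peaks within a list.

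The strongest site of both replicates lay upstream of rpl-3, which encodes a protein of the large ribosomal subunit. Its peak spans chromosome III, 3867346 to 3867828 (ce11), in intergenic sequence 283 bp upstream of the annotated 5′ end, with a signal of 13097 in the main list, 6728 in replicate 1 and 6433 in replicate 2. It was followed by a site 120 bp upstream of brc-1, the BRCA1 orthologue, on the same chromosome at 3862856 to 3863361, with a signal of 7840. The third, with 6943, lay in the promoter windows of both F01G4.6 and the prefoldin gene pfd-1 on chromosome IV at 11149535 to 11150000. The promoter of mdh-2, a malate dehydrogenase gene, had 6007, and that of acs-2, an acyl-CoA synthetase gene of fatty acid oxidation, had 5166.

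The 25 strongest sites found in both replicates had signals from 3523 to 13097. Further ribosomal protein genes stood among them. A site shared by rpl-20 and Y17G9B.5 had 5078, rpl-35 had 4650 and rpl-15 had 3833. Other promoter sites were those of tasp-1 (4968), cdc-48.1 (4632), the splicing helicase gene mog-4 (4432), the Pumilio-family gene puf-9 (3870), tag-340 (3841) and egg-5 (3747), the last of which lies within 500 bp of the SL2 RNA gene sls-2.4. Several lay away from promoters. A site in an annotated 5′ UTR exon of srh-2 (chromosome V, 731247 to 731799) had 6263 and lay 3228 bp downstream of that gene's 5′ end. Intergenic sites next to F21C10.10 (5316), D2023.4 (4402) and the hypoxia factor gene hif-1 (4028, at 1986 bp upstream), and an intron site of C34B4.2 (3887) complete the 5 strongest over 1000 bp from any 5′ end. Those next to F58D12.3 (3876), K08F11.1 (3702 and 3649) and ins-13 (3550), an intron site of epg-9 (3646) and a 3′ UTR site of adal-1 (3523) make up the rest of the 25. All of these but the weaker K08F11.1 site, at 744 bp, also lie over 1000 bp from a protein-coding 5′ end. The ins-13 site lies within 500 bp of the SL2 RNA gene sls-2.2.

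The tagged gene held many sites. Within 1000 bp of nhr-19 (chromosome II, 9598180 to 9605526, minus strand) there were 9, in worms that also carry this gene on the transgene, from which signal at the native gene cannot be separated. The strongest, 9603416 to 9603806 in an intron, had a signal of 3268 and rank 31 of all sites, with 1847 in replicate 1 and 1457 in replicate 2. A further pair of intron sites had 1275 and 957, and the site 34 bp upstream of the 5′ end had 434. The rescue marker gene unc-119 (chromosome III, 10902641 to 10908935) had no site; its strongest candidate had a signal of 94.4 at an IDR of 0.156.

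**Figure D1:**
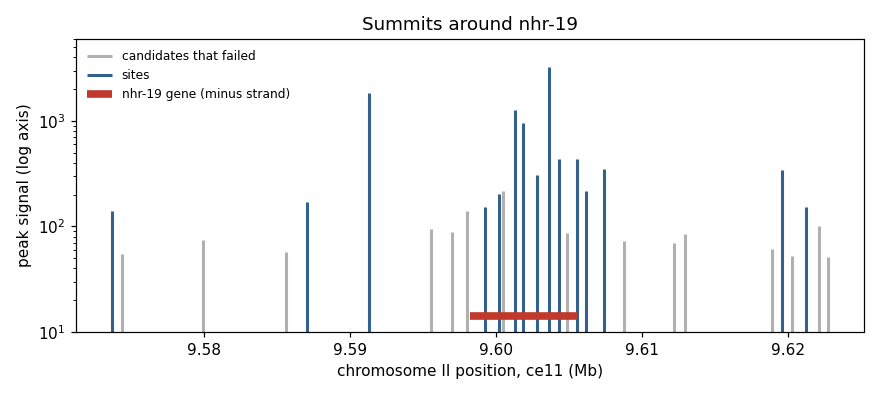
Peak signal (authors' units, log axis) of summits on chromosome II around nhr-19, by position in Mb on ce11; blue lines are sites, grey lines are candidates that failed the threshold and the red bar is the gene. The highest line, with 3268, lies inside the gene.

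The replicates shared most of their sites. Of the 3729 sites of replicate 2, the smaller list, 3074 (82.4%, Wilson interval 81.2 to 83.6%) had a summit of replicate 1 within 200 bp. The mean after circular shifts was 1.52% (permutation p = 0.001, one-sided, the smallest the shifts can give). Shifted sites lose the preference for promoters. This mean therefore does not show what 2 unrelated lists that both favour promoters would share. Shared sites had a median signal of 209 in replicate 1, and sites without a partner had 102. Of the 694 sites of replicate 1 without a partner, 612 were in the ranked list of replicate 2, and 82 were in neither list of replicate 2; 83 sites of replicate 2 were likewise absent from both lists of replicate 1. The strongest of these replicate 1 sites lay in an intron of ppfr-1 (316) and upstream of Y54G11A.2 (305) and gcn-1 (288), and in replicate 2 in an intron of H18N23.2 (319) and next to sup-35 (264) and aipl-1 (251).

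Across 3069 matched sites the signals of both replicates correlated with a Spearman rho of 0.919 and a Pearson r of 0.943 on the log2 scale (permutation p = 1e-05 for each, 2-sided, the smallest the permutations can give). This is a correlation across sites, which are not independent replicates. A site could enter more than 1 pair, and with each site matched once, a choice made after the data were seen, rho was 0.925 over 3049 pairs.

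**Figure D2:**
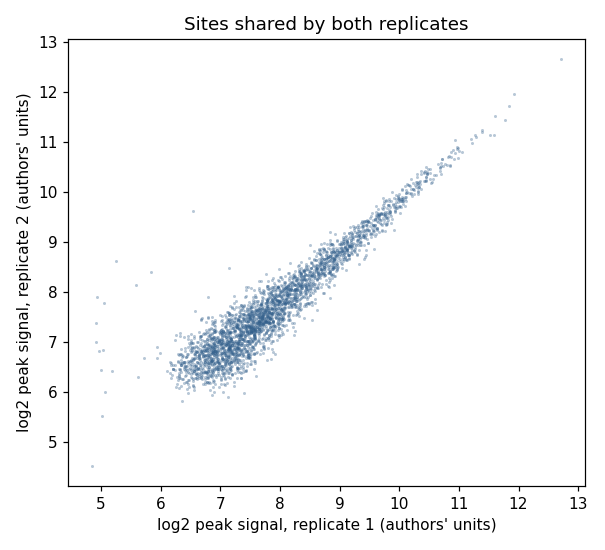
Log2 peak signal (authors' units) of replicate 1 on the horizontal axis and replicate 2 on the vertical axis; each point is 1 of the 3069 matched sites. Most points lie near the diagonal, with a Pearson r of 0.943, and some lie far from it.

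The list from true replicates and the list from pooled pseudoreplicates held largely the same sites. Of the 4452 pooled sites, 4052 (91.0%, Wilson interval 90.1 to 91.8%) were in both. Shared sites had a median signal of 302, and the 400 sites of the pooled list alone had 136. No test applied to this overlap, as both lists come from the same reads.

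Sites lay in promoters more often than candidates that failed the threshold. Promoters held 2210 sites (48.8%, Wilson interval 47.3 to 50.2%) against 27.2% of candidates and 26.4% of the genome, a log2 odds ratio of 1.35 ± 0.05 (SE; Fisher's exact test, adjusted p = 7.69e-159). Exons held 2.89% of sites against 20.7% of candidates (log2 odds ratio −3.13 ± 0.13, exact test, adjusted p = 1.89e-231), and introns 21.4% against 28.3% (−0.53 ± 0.06, adjusted p = 1.41e-20). Sequence near non-coding RNA genes held 8.21% against 4.23% (1.02 ± 0.10, exact test, adjusted p = 5.18e-24). The share in other intergenic sequence was 18.7% against 19.6% (log2 odds ratio −0.088, exact test, adjusted p = 0.160). That class passed as lower in 5 alternatives, among them the strongest 50% of sites (−0.43, exact test, adjusted p = 9.85e-07) and each replicate alone (both −0.21).

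**Figure D3:**
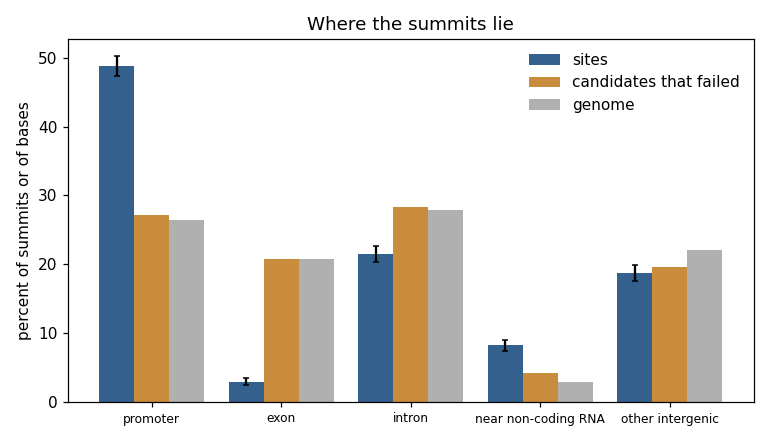
Percent of summits in each annotation class for the 4530 sites (blue, with 95% Wilson intervals) and the 15775 candidates that failed the threshold (orange), and percent of bases of the genome (grey). Sites exceed both others in promoters, at 48.8%, and lie below them in exons, at 2.89%.

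Promoter sites were also stronger. Their mean log2 signal was 8.50 ± 1.15 (SD over 2210 sites) against 8.13 ± 1.06 for the 2320 others, a difference of 0.38 (permutation p = 1e-05, 2-sided, the smallest the permutations can give). Medians were 320 and 237.

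By chromosome, sites were densest on III (55.4 per Mb) and X (53.1 per Mb) and least dense on V (37.4 per Mb). Against candidates, III was higher (log2 odds ratio 0.24 ± 0.07, Fisher's exact test, adjusted p = 9.61e-04), X was higher (0.20 ± 0.06, adjusted p = 0.00222) and V was lower (−0.43 ± 0.06, adjusted p = 3.38e-11). Chromosomes I, II and IV had 667, 691 and 685 sites and did not pass the test, with adjusted p of 0.541, 0.810 and 0.981; against chromosome length IV was lower (−0.25, exact binomial test, adjusted p = 4.54e-05). In the central 50% of the autosomes lay 62.6% of autosomal sites against 46.2% of candidates (log2 odds ratio 0.96 ± 0.06, Fisher's exact test, p = 2.58e-68). The difference of X did not pass the test in the strongest 50% of sites (0.06, exact test, adjusted p = 0.542) or in replicate 2 alone (0.07, adjusted p = 0.393).

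Of 6683 genes with a site or candidate in the promoter window, 2810 were bound. Ribosomal protein genes were bound most often of the lists, with 68 of 76 (89.5%, Wilson interval 80.6 to 94.6%). Translation factor genes followed with 23 of 30, oxidative phosphorylation genes with 21 of 28, heat shock and chaperone genes with 25 of 37 and proteasome genes with 16 of 24. Central carbon metabolism and muscle marker genes each had 22 of 36. At the other end, 17 of 205 chemoreceptor genes and 6 of 68 C-type lectin genes were bound.

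The log2 odds ratio was 3.51 ± 0.53 (SE) for ribosomal proteins (Fisher's exact test, adjusted p = 7.39e-17), 2.12 ± 0.61 for translation factors (adjusted p = 6.50e-04), and 1.99 ± 0.61 for oxidative phosphorylation (adjusted p = 0.00297). For heat shock and chaperones, 67.6% were bound against 41.9% of the other genes (Fisher's exact test, adjusted p = 0.00695). Among the translation factors, eef-1G had a signal of 3429, the eIF5A gene iff-2 had 3264, the elongation factor gene eef-1A.1 had 2114 and eif-3.C had 2094. The cytochrome oxidase gene cox-5A had 3170, the succinate dehydrogenase gene sdha-1 had 2264 and the ATP synthase gene atp-1 had 1740. The mitochondrial chaperonin gene hsp-60 had 2804, cct-8 and cct-1 of the cytosolic chaperonin had 2663 and 2537, and hsp-3 had 1936. Of the genes named here, mdh-2, tasp-1, tag-340, rpl-15, iff-2, eef-1G, eef-1A.1, atp-1, hsp-60, cct-8, cct-1, rpn-3, pbs-1, aco-2, htz-1, nhr-47, nhr-68 and cpt-2 have a site that lies also in the promoter window of a neighbouring gene. Proteasome genes (1.43 ± 0.61, exact test, adjusted p = 0.0486), such as rpn-3 (1813) and pbs-1 (887), and central carbon metabolism and muscle markers (both 1.10 ± 0.49, adjusted p = 0.0497), such as aco-2 (1619) and the actin gene act-1 (568), passed the test narrowly. With each site given only to its nearest gene, a choice made after the data were seen, heat shock and chaperone genes were no longer higher (−0.10, exact test, adjusted p = 0.927). Of the 7 higher lists, ribosomal proteins, translation factors and oxidative phosphorylation were called in 11 of 11 alternatives, heat shock and chaperones in 10, muscle markers in 8 (not without replicate 2), central carbon metabolism in 7 (not without replicate 2) and the proteasome in 7 (not without replicate 1).

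Chemoreceptors (log2 odds ratio −3.03 ± 0.36, Fisher's exact test, adjusted p = 3.79e-26), C-type lectins (−2.82 ± 0.60, adjusted p = 1.40e-08), F-box, MATH and BATH genes (17 of 83, −1.48 ± 0.39, adjusted p = 3.05e-04), intestine markers (6 of 44, −2.11 ± 0.61, adjusted p = 4.55e-04) and homeobox genes (5 of 32, −1.87 ± 0.67, adjusted p = 0.00683) were lower. Molting genes (4 of 24, exact test, adjusted p = 0.0336), insulin signalling genes (3 of 19, adjusted p = 0.0486) and neuropeptide genes (6 of 29, adjusted p = 0.0486) were also lower. Chemoreceptors were called in 11 of 11 alternatives, intestine markers, C-type lectins and F-box, MATH and BATH genes in 10, homeobox genes in 8 (not without replicate 2), neuropeptides in 7, molting genes in 6 (not without replicate 2) and insulin signalling genes in 4 (not without replicate 1 or 2). Against circular shifts of the sites over the genome, a test without the candidate background, 15 lists were higher and 1, chemoreceptors, was lower (permutation test). All protein-coding genes together had a log2 ratio to the shifts of 1.16, since sites favour promoters. Passing this test as higher therefore does not set a list apart from other genes. The 7 lists higher against candidates had 2.52 to 3.59. The shifts are 1 of the 11 alternatives counted above, so those counts favour higher lists over lower ones. They were the only alternative lost by intestine markers, C-type lectins and F-box, MATH and BATH genes.

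The remaining 13 lists did not pass the test against candidates. Of them, 8 passed as higher against circular shifts, with log2 ratios, beside the 1.16 of all genes, of 2.50 for cell cycle, 2.24 for pan-neuronal markers, 2.22 for the vacuolar ATPase, 2.00 for histones, 1.76 for heterochronic and Wnt genes, 1.61 for lipid metabolism, 1.20 for nuclear hormone receptors and 1.14 for xenobiotic metabolism; differences from the value of all genes were not tested. Xenobiotic metabolism was lower against candidates in the pooled list (−0.92, exact test, adjusted p = 0.0104), in the strongest 50% of sites (−2.31, adjusted p = 6.07e-06) and without replicate 1 (−0.91, adjusted p = 0.0118) or 2 (−1.11, adjusted p = 0.00412). Histone genes had 21 of 35 bound (exact test, adjusted p = 0.0674), with his-37 at 2547 and htz-1 at 1933. Cell cycle genes had 22 of 37 (exact test, adjusted p = 0.0719), with the sliding clamp gene pcn-1 at 1858. Both passed as higher against candidates in the pooled list (1.15 for histones and 1.11 for cell cycle), without replicate 1 (1.97 and 1.48) and with 2000 bp upstream (1.11 and 1.20), and with all genes as background (1.10 and 2.04); cell cycle passed also without replicate 2 (1.57) and with the nearest gene only (1.19). Pan-neuronal markers passed as higher with 2000 bp upstream (1.70), all genes as background (1.85) and the nearest gene only (1.73), the vacuolar ATPase with all genes as background (1.95), and hypodermis and seam markers as lower in the pooled list (−2.81, exact test, adjusted p = 0.0165) and at an IDR of 0.05 (−2.02, adjusted p = 0.0479). Nuclear hormone receptor genes had 37 bound, 35.6% of their background (exact test, adjusted p = 0.258), with nhr-47 at 1403 and nhr-68 at 1008. Lipid metabolism genes had 22 of 55 (exact test, adjusted p = 0.837), with acs-2 at 5166 and cpt-2 at 1455. Bound counts were 8 of 17 for the vacuolar ATPase, 11 of 18 for pan-neuronal markers, 8 of 14 for heterochronic and Wnt genes, 19 of 52 for cuticle collagens, 31 of 96 for xenobiotic metabolism, 10 of 31 for other developmental transcription factors, 11 of 34 for pharynx markers, 8 of 20 for germline and P granule genes and 2 of 13 for hypodermis and seam markers. Their adjusted p in the exact test ranged from 0.0939 to 1. In the pharynx list, the 4 bound genes of highest signal were pqn-51, pqn-59, pqn-27 and pqn-70. Whether these genes mark the pharynx was not examined.

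**Figure D4:**
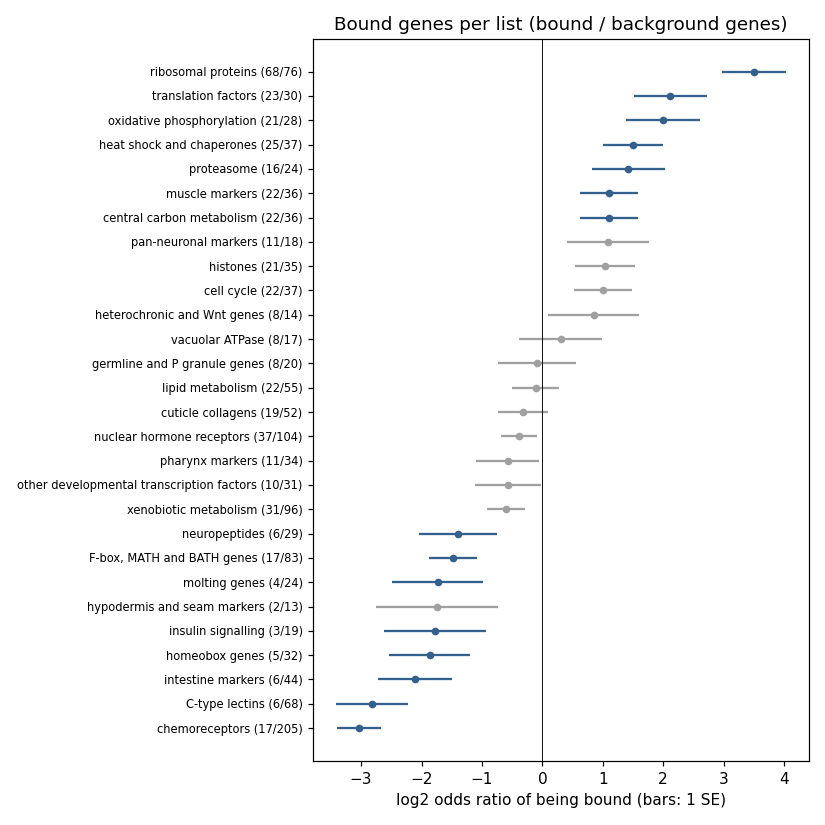
Log2 odds ratio of being bound for each gene list, with bars of 1 SE and the number of bound and background genes beside each name; blue lists pass the test (adjusted p under 0.05) and grey lists do not. Ribosomal proteins stand at 3.51 and chemoreceptors at −3.03.

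The nuclear receptor half-site searched for, RGKTCA, was not more frequent at summits than beside them. Whether NHR-19 itself prefers this sequence was not tested, so its absence does not show a lack of direct binding. The half-site lay within 50 bp of 13.7% of summits, against 13.2% of the left flanks (paired log2 ratio 0.06 ± 0.09 SE, exact McNemar test, adjusted p = 0.698) and 13.4% of failing candidates. From the strongest to the weakest of 4 equal groups of sites ranked by signal, it lay at 10.7, 15.6, 14.7 and 13.7%. The second group had the highest share, so the half-site did not change steadily with signal. The log2 odds ratio between the strongest and the weakest group was −0.41 ± 0.19 (Fisher's exact test, adjusted p = 0.0496). The GAGA repeat (GAGAGA) lay at 25.9% of summits against 8.65% of flanks, and the E-box CACGTG at 7.75% against 1.79%. The CG-rich box CCGCCC was at 5.63% against 2.34%, and the E2F-like site at 1.46% against 0.353%.

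Paired log2 ratios compare sites with the word only at the summit with sites with it only in the flank. They were 1.97 ± 0.10 for the GAGA repeat (exact McNemar test, adjusted p = 1.85e-108), 2.26 ± 0.19 for the E-box (adjusted p = 9.10e-43), 1.36 ± 0.17 for the CG-rich box (adjusted p = 9.73e-16) and 2.15 ± 0.42 for the E2F-like site (adjusted p = 2.23e-08). The splice acceptor word fell from 18.1% of flanks to 5.61% of summits (exact McNemar test, adjusted p = 2.22e-78). The forkhead site fell from 11.5% to 7.99% (exact McNemar test, adjusted p = 3.26e-08), but against candidates, at 8.74%, it did not pass (exact test, adjusted p = 0.170). The reversed half-site, a control of the same composition, fell from 14.4% to 11.1% (paired log2 ratio −0.43, exact McNemar test, adjusted p = 6.11e-06). GATA sites were at 21.9% of summits and 22.4% of flanks (exact test, adjusted p = 0.698). They were lower in the strongest 50% of sites (paired log2 ratio −0.43, exact test, adjusted p = 1.92e-04) and higher with windows of 100 bp (0.20, adjusted p = 0.00231). Between the strongest and weakest of 4 equal groups, their log2 odds ratio was −1.13 ± 0.16 (Fisher's exact test, adjusted p = 9.49e-13). AP-1 sites were at 0.817% and 0.993% (exact test, adjusted p = 0.698), and direct, inverted and everted repeats of the half-site were at 9, 0 and 1 summits against 7, 1 and 2 flanks. Summit windows had 45.8% GC against 35.9% in left flanks and 39.9% at failing candidates. Whether this difference accounts for the excess of the E-box, the CG-rich box and the E2F-like site was not tested.

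Among 2080 6-mers, counted with their reverse complements, 817 were more frequent at summits and 521 less frequent. After GAGAGA, the word with the smallest p of those more frequent was ACGCAG, at 14.8% of summits against 2.27% of flanks (paired log2 ratio 2.87 ± 0.16 SE, exact McNemar test, adjusted p = 9.70e-105). It lay at 20.8% of the strongest and 9.10% of the weakest of 4 equal groups of sites ranked by signal (log2 odds ratio 1.39 ± 0.18, Fisher's exact test, adjusted p = 3.03e-14). The overlapping words GACGCA and AGACGC were at 636 and 605 summits. A/T-rich words such as AAAATT fell from 39.6% to 15.4%.

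**Figure D5:**
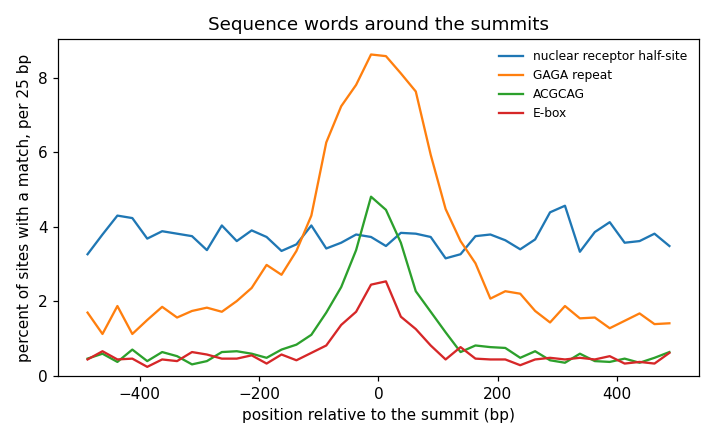
Percent of the 4530 sites with a match per 25 bp (vertical axis) by position relative to the summit in bp, for the nuclear receptor half-site, the GAGA repeat, ACGCAG and the E-box. The last 3 peak at the summit, where the half-site, at 13.7% of summits within 50 bp, shows no peak.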

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

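The looser IDR, the nearest-gene mapping and the pairing of each site once were chosen after the data were seen; the other alternatives were set before. Replicate overlap, signal correlation, list overlap, signal by promoter position and the promoter class kept direction and side of the threshold in all their alternatives, and total counts of called motifs, 6-mers and lists stayed within 1.5 times. The split of called lists did not: from 7 higher and 8 lower it went to 15 and 1 under circular shifts, 11 and 7 with all genes as background, 4 and 6 in the strongest 50%, 4 and 8 with 500 bp upstream, 10 and 5 with 2000 bp, and 8 and 5 with the nearest gene only. Sites by chromosome, for X, did not: the log2 odds ratio was 0.059 in the strongest 50% of sites and 0.073 to 0.16 without replicate 1 or 2. The cause was not tested. Over all alternatives of the list tests, 34 calls were lost and 28 values passed newly, 3 of these in the opposite direction. The forkhead call was lost against candidates (−0.14), and GATA passed newly as lower in the strongest 50% (−0.43). Changes of direction follow, as log2 values; the cause was not tested except where the construction shows it. Pooled list: collagens 0.064, lipid metabolism 0.22, germline 0.33. Strongest 50%: chromosome II 0.057, germline 0.67, direct repeat −0.49, AP-1 0.31. Without replicate 1 or 2: lipid metabolism 0.56 and 0.021, germline 0.13 and 0.43; half-site −0.059 without replicate 1 (0.036 without replicate 2, which keeps the direction); AP-1 0.35 without replicate 2. IDR 0.05: chromosome IV −0.065, lipid metabolism 0.34. Window of 500 bp upstream: vacuolar ATPase −0.079; of 2000 bp: lipid metabolism 0.31. All genes as background: lipid metabolism 0.61. Nearest gene only: nuclear hormone receptors 0.075, other developmental transcription factors 0.071, heat shock and chaperones −0.10. Circular shifts, which compare with the whole genome and not with candidates, and where all genes have 1.16: nuclear hormone receptors 1.20, other developmental transcription factors 0.43, collagens 0.79, lipid metabolism 1.61, xenobiotic metabolism 1.14, pharynx 0.68, germline 0.39. Chromosome length as background: I −0.035, II 0.0018, IV −0.25, which passes as lower. Motif windows of 100 bp: half-site −0.061, direct repeat −0.35, GATA 0.20, which passes as higher, AP-1 0.35. Candidates as background: GATA 0.10. With depth unknown, sites absent from a replicate's list are not shown to be unbound.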

Other observations

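The counts of non-coding genes, the tests on the nhr-19 locus, those on base composition of words, the shares bound by GC class and the share of ribosomal protein summits with a half-site were chosen after the results were seen. The comparisons of other words at ribosomal protein summits were not written down first. The remaining tests were. Genes of tRNAs and snoRNAs had a site more often than protein-coding genes. Of 612 tRNA genes, 300 had a site within 500 bp, and of the 456 with a site or a candidate 65.8% (Wilson interval 61.3 to 70.0%) had a site, against 2810 of 6683 protein-coding genes with either in the promoter window (log2 odds ratio 1.40 ± 0.15 SE, Fisher's exact test, adjusted p = 1.84e-22; the windows differ). For snoRNA genes it was 61.0% of 205 (1.10 ± 0.21, exact test, adjusted p = 1.73e-07) and for snRNA genes 40 of 65 (1.13 ± 0.37, adjusted p = 0.00331), but 16 of these 40 are SL2 RNA genes, and the other snRNA genes had 24 of 49 (0.41 ± 0.41, exact test, p = 0.384). Neighbouring genes can share 1 site. Pseudogenes were lower, with 71 of 526 (−2.21 ± 0.19, exact test, adjusted p = 3.36e-42), and microRNA genes, with 36 of 92, did not pass the test (adjusted p = 0.597).

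Among the spliced leader genes, 16 of 18 SL2 RNA genes had a site within 500 bp. The strongest were at sls-2.4 (signal 3747, rank 20), sls-2.2 (3550, rank 24) and sls-2.1 (3345, rank 28). Those at sls-2.4 and sls-2.2 are the sites named above by egg-5 and ins-13. None of the 12 SL1 RNA genes had a site or a candidate nearby; whether reads can be placed at these genes was not examined.

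Ribosomal protein genes were bound more often than other genes with a site or candidate, and a technical source may lie behind this. GC content was taken over 200 bp either side of the passing summit of bound genes and of the strongest candidate of the others. The place measured thus depends on whether a gene was bound. Combining within 10 classes of it gave a log2 odds ratio of 3.55 (95% interval 2.49 to 4.61) against 3.51 without this step. This step also left translation factors at 2.12 and so decides nothing. But other genes were bound in 32.12 to 46.96% of cases across these classes. The share of ribosomal protein genes was 89.5% (Wilson interval 80.6 to 94.6%). This argues against GC content over that window as the whole cause. GC content within 50 bp of the summit, as compared with flanks above, was not used for these classes. Only the strongest summit within 500 bp of each gene's annotated 5′ end was placed. Of 64 ribosomal protein genes with one, 1 had it downstream (1.56%, Wilson interval 0.276 to 8.33%). This argues against the strongest signal near the 5′ ends lying inside the annotated gene bodies. Weaker summits downstream were not counted. Other bound genes also seldom had their strongest summit downstream (247 of 2230, 11.1%), so a low share is not particular to ribosomal protein genes. Signal that comes with strong transcription but lies upstream of the annotated 5′ end is not addressed by this test. Exact half-sites at most of the strongest summits of ribosomal protein genes are argued against too. Taking each gene's strongest summit, with shared ones counted once, 5 of 65 (7.69%, Wilson interval 3.33 to 16.8%) had one. The log2 odds ratio was −0.66 (95% interval −1.93 to 0.62) against other bound genes. Signal that any tagged protein gives at open promoters was not tested, since no other protein's data were used here.

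The 9 sites within 1000 bp of nhr-19 were more than at any of the 1190 genes within 20% of its length, whose highest count was 8 (percentile 100), so gene length does not account for them. Extra copies of the transgene's genomic segment are a candidate explanation that the flanks do not decide. The 15 kb on each side held 5 sites, at percentile 95.5 of the flanks of all protein-coding genes. That is just past the bound of 95 set for this test. But nhr-19 lies in the centre of its chromosome, and autosome centres held 62.6% of autosomal sites against 46.2% of candidates. The compared genes were not matched for this, so the test cannot tell extra copies from a locally high density of sites. The rescue marker gene unc-119 had no site, and whether the marker holds this gene's native sequence was not examined. The extent of the genomic segment is not given in the sources used here, and binding of the protein to its own gene was not tested.

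GAGAGA, a motif fixed before the data were examined, stood at percentile 99.2 of the summit-to-flank ratios of words with the same GC and CpG content, which argues against base composition as the whole cause. ACGCAG was picked from all 6-mers for its difference, so the same ranking would not test it. The 4 words of the nuclear receptor half-site had a median percentile of 56.0 in the same test, with AGGTCA at 80.0 and AGTTCA at 24.3. The reversed half-site, of the same composition, fell (paired log2 ratio −0.43 against flanks, log2 odds ratio −0.56 against candidates). The half-site did not (0.064 and 0.034 by the same measures). As these comparisons point different ways, an excess hidden by composition cannot be told apart from none. Among the strongest summits of bound genes, GAGAGA was at 10.8% of ribosomal protein summits against 22.7% of those of other genes (Fisher's exact test, unadjusted p = 0.0225). ACGCAG was at 18.5% against 16.4% (exact test, unadjusted p = 0.613) and CACGTG at 3.08% against 5.65% (exact test, unadjusted p = 0.581). Apart from half-sites and these words, no biological explanation was tested.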
